A study of Danio rerio with 12 samples.

How the data were processed

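Total RNA sequencing of whole zebrafish embryos at the tailbud stage was analysed in 12 libraries, 3 in each of 4 groups. Embryos carried a control morpholino or a morpholino against tif1g (the gene trim33), and were kept in DMSO or in leflunomide, an inhibitor of the pyrimidine synthesis enzyme encoded by dhodh. Per the labels, 1 ng of morpholino was injected at the 1 to 2 cell stage, treatment with 7 µM leflunomide or DMSO ran from 5.3 to 10 hours after fertilisation, and each sample pooled 109 embryos of the TU strain. The series description says that the embryos of a clutch were divided over the treatments. Whether each replicate number is a clutch of its own is not given in the sources used here. The p-values therefore measure the spread between these pooled samples as far as the labels describe it.

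The deposited values are raw read counts per gene, whole numbers for 32520 Ensembl genes. Per the submitters' processing notes, FastQC and cutadapt were used on the reads, TopHat2 2.0.11 aligned them to genome build GRCz11, HTSeq counted them, and Cufflinks 2.2.1 was run beside it. The libraries were directional and depleted of ribosomal RNA. The strand setting of the counting and the annotation release are not given in the sources used here, so counts of genes that overlap on opposite strands carry an unknown share of each other's reads. Total counts ran from 27574593 to 32088082 per library. Over genes with at least 20 counts in a pair of libraries, the chi-square per degree of freedom between replicates was 7.09 to 15.0. Abundant genes weigh most in it, and for them counting error was a small part of the spread between replicates. No genome sequence or gene coordinates were used here, so genes are given by symbol and identifier without a position, and transcript length and GC content were not analysed here.

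Symbols came from a table of gene names that covered 29201 of the 32520 identifiers. Names in capitals were written in lower case, and a list symbol ending in a or b was matched to the name without that letter where only that name existed. Of the tested genes, 1523 had no symbol. Where 2 genes share a symbol, the Ensembl identifier is given.

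Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left 21400 of the 30339 genes with a count. Counts were scaled with TMM factors, and 1 model with 4 group means was fitted to the 12 libraries with the robust quasi-likelihood fit of edgeR (biological coefficient of variation 0.113). Comparisons were tested with edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over the 21400 genes. A gene was called at an adjusted p under 0.05 with no fold minimum. Adjusted p-values given for genes come from this test. Changes are log2 fold changes with a standard error taken from the F statistic, from 3 libraries a group, and levels are TMM-scaled CPM, counts scaled to a common library total (mean ± SD, n = 3). The comparisons were the knockdown in DMSO and in leflunomide, leflunomide in control and in tif1g embryos, the interaction of both, and tif1g leflunomide against control DMSO.

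Named genes were taken by a rule. It takes trim33, dhodh, gata1a and tal1 in every comparison. It takes the 10 genes with the largest rise and the 10 with the largest fall in the 3 main comparisons (the knockdown in DMSO, and leflunomide in each kind of embryo), and 5 each way in the others. These had to be called, have a mean log2 CPM of at least 1 and move in the same direction in each of the 3 replicate numbers, and unnamed genes and clone names were skipped. It also takes up to 4 members of each gene list with the smallest p. Some genes that this rule takes, and 1 of the gene lists, are not reported here.

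The 38 gene lists covered several themes. Blood and stress lists were erythroid and heme genes, hemangioblast, endothelial and myeloid genes, the integrated stress response, heat shock and unfolded protein response, interferon and innate immune genes, hypoxia response, aryl hydrocarbon receptor targets, and immediate early and MAPK response genes. Metabolic lists were nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, coenzyme Q synthesis, pyrimidine synthesis and salvage, purine synthesis, glycolysis, the TCA cycle and pyruvate entry, and cholesterol synthesis. Expression and growth lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis and RNA polymerase I, transcription elongation machinery, and cell cycle. Signalling and stage lists were Nodal and TGF-beta targets, BMP targets, maternal transcripts, blastula to early gastrula zygotic genes, and genes that rise at the end of gastrulation. Tissue lists were primordial germ cells, endoderm, axial mesoderm and notochord, paraxial mesoderm and somites, lateral and intermediate mesoderm, neural plate, neural crest, epidermal ectoderm, enveloping layer, yolk syncytial layer and hatching gland. Each was tested with camera in limma 3.58.1 at its preset correlation of 0.01 with Benjamini-Hochberg adjustment over the 38 lists, again with an estimated correlation, and with fry. Camera tests a list against the other genes and fry tests it against no change, so the ranges over alternatives span both questions. The comparisons, lists, naming rule, thresholds and most alternatives were fixed before the data were examined.

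Samples with the same replicate number correlated at 0.156 to 0.274 after the group means were removed (18 pairs), and those with different numbers at -0.170 to -0.0273 (36 pairs), so the number was also fitted as a replicate block. Other alternatives were RLE factors, library totals alone, DESeq2 1.42.0, limma voom, no filter, a stricter filter, the fit without the robust option, the compared groups alone, a minimum of 2-fold, and the omission of each library or replicate number. The share of an effect carried into the other arm was measured by cross-fitting: genes were selected without 1 replicate number, and their median signed change was taken in that number in both arms. Leflunomide carried into tif1g embryos, library totals alone, omission of a whole number, omission of libraries in the list tests, flips within pairs, and the ribosomal protein list without kinases were chosen after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

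The method was tested on simulated data of 21400 genes with the means and dispersions of the real ones. Each gene was drawn on its own, without correlation between genes or an effect of the replicate number. Where leflunomide effects were simulated in both kinds of embryo, the comparison in control embryos recovered 7, 19, 38 and 44 of 50 genes changed by 1.25, 1.5, 2 and 4-fold, with 9 false calls. For the interaction it recovered 1, 9, 25 and 42 of 50, with 11 false calls, and comparisons without a change gave 0 calls. Far fewer genes were changed here than were called in most of the real comparisons, and the cut-off depends on that share. The recovered counts may therefore not carry over to the real data. A list of 40 genes shifted by 0.3 on the log2 scale was called with the preset correlation (adjusted p = 7.59e-17) and with an estimated one (adjusted p = 0.00382), and 0 of 37 unshifted lists were called. Lists whose genes vary together were not simulated, so this count does not speak for false calls among the real lists. Cross-fitting returned 69.0% ± 1.27 (SD) where 70% of an effect was carried over. That SD likewise leaves out any effect of the replicate number.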

Results

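Total RNA of whole embryos at the tailbud stage was counted in 12 libraries. They formed 4 groups of 3: control morpholino in DMSO, control morpholino in leflunomide, tif1g morpholino in DMSO and tif1g morpholino in leflunomide. The labels describe tif1g (trim33) as the gene knocked down. The question that the design poses is which transcripts depend on trim33 and on pyrimidine synthesis, and whether inhibiting the latter alters the effect of the former. Library totals were 29845700 to 32088100 counts in control DMSO, 27574600 to 29182900 in control leflunomide, 28652400 to 28972000 in tif1g DMSO and 27714900 to 29691000 in tif1g leflunomide. The first principal component held 35.8% of the variance and parted the morpholinos, with control libraries at -47.9 to -27.9 and tif1g libraries at 31.0 to 42.9. The second held 14.3%.

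The trim33 transcript itself (ENSDARG00000016181) was more abundant in embryos with the tif1g morpholino. It stood at 74.9 ± 5.03 CPM (SD, n = 3) in control DMSO, 81.5 ± 3.64 in control leflunomide, 380 ± 12.5 in tif1g DMSO and 422 ± 8.88 in tif1g leflunomide. The rise was 2.34 ± 0.06 (SE) on the log2 scale in DMSO (5.08-fold, adjusted p = 4.98e-15, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and 2.37 ± 0.06 in leflunomide (adjusted p = 4.43e-15), and all 6 tif1g libraries lay above all 6 control libraries. The morpholino sequence holds the complement of an ATG, as those that block translation do, for which the RNA level would not measure the knockdown. Its position on the transcript was not tested. Leflunomide changed trim33 by 0.12 ± 0.06 in control embryos (adjusted p = 0.14) and by 0.15 ± 0.06 in tif1g embryos (adjusted p = 0.218). With the replicate block these passed at adjusted p = 0.0491 and 0.031, and the range over the alternatives was 0.00565 to 0.422 in control and 0.031 to 0.6 in tif1g embryos.

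The dhodh transcript (ENSDARG00000051889), which encodes the mitochondrial enzyme of pyrimidine synthesis that leflunomide inhibits, fell after the knockdown. It changed by -0.92 ± 0.10 in DMSO (adjusted p = 2.22e-06) and by -0.63 ± 0.10 in leflunomide (adjusted p = 0.000166), from 23.4 ± 1.93 and 22.0 ± 2.4 CPM in control embryos to 12.4 ± 0.936 and 14.2 ± 0.874. Leflunomide moved dhodh by -0.09 ± 0.10 in control embryos and by 0.20 ± 0.10 in tif1g embryos, and neither change passed (adjusted p = 0.594 and 0.419). The tal1 transcript (ENSDARG00000019930), which encodes a transcription factor that blood and vessel precursors need, fell in DMSO by 3.13 ± 0.99 on the log2 scale (adjusted p = 0.0368). Its level was 2.49 ± 2.33 CPM in control DMSO and 0.28 ± 0.0939 in tif1g DMSO. The tal1 call was lost without control_DMSO replicate 1 (adjusted p = 0.11) and without tif1g_DMSO replicate 1, 2 or 3 (0.0895, 0.121 and 0.0914), and its adjusted p ranged from 3.4e-05 to 0.206 over the alternatives. In leflunomide the tal1 change was -2.30 ± 0.82 (adjusted p = 0.0756), which passed with the replicate block (adjusted p = 0.000128, range over the alternatives 0.000128 to 0.272). The erythroid factor gata1a had 3 to 14 counts a library and was not tested.

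**Figure D1:**
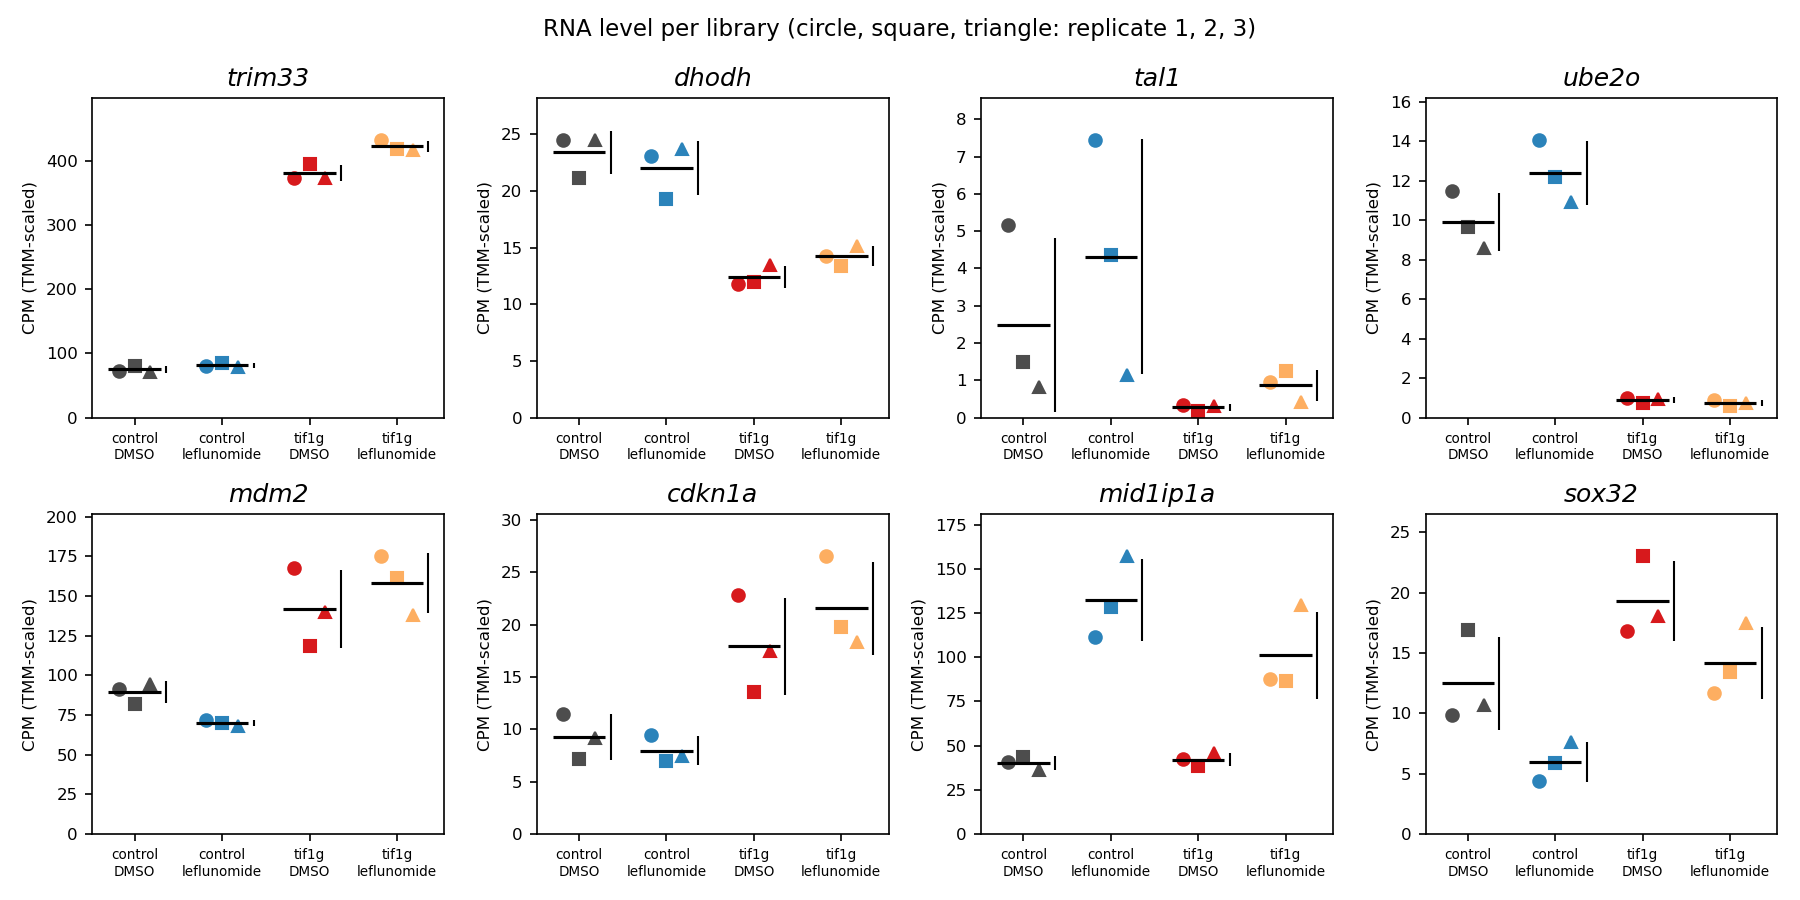
TMM-scaled CPM (vertical axes) of 8 genes in the 4 groups, with 1 point per library (circle, square and triangle for replicates 1, 2 and 3), a bar at the group mean and a vertical line for the SD. The trim33 points of the tif1g groups, at means of 380 and 422 CPM, lie above the control groups at 74.9 and 81.5 CPM.

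The knockdown in DMSO, the comparison that asks which transcripts depend on trim33, raised and lowered transcripts by large factors. The largest rise was that of bmf2, which encodes a pro-apoptotic member of the Bcl-2 family, at 5.40 ± 0.48 on the log2 scale (0.114 CPM in control DMSO, 5.04 in tif1g DMSO, adjusted p = 3.51e-07). The endocytic lectin receptor gene ly75 rose by 3.12 ± 0.08 (8.33 to 72.2 ± 3.54 CPM), the avidin gene avd by 3.04 ± 0.20, vstm2b by 3.04 ± 0.27 and the prostaglandin reductase gene ptgr1.2 by 2.87 ± 0.29. Other large rises were those of strc1 (2.57 ± 0.17), the sphingolipid transporter family gene spns3 (2.53 ± 0.25), the phosphoinositide phosphatase gene inpp4a (ENSDARG00000070995, 2.51 ± 0.29), ly6pge (2.46 ± 0.30) and the monocarboxylate transporter family gene slc16a12 (2.43 ± 0.19). The largest fall was that of ube2o (ENSDARG00000100674), a ubiquitin-conjugating enzyme gene, at -3.47 ± 0.20 (9.90 ± 1.48 to 0.887 ± 0.138 CPM, adjusted p = 4.03e-10). After tal1 came the slow muscle myosin gene smyhc1 (-3.05 ± 0.73), the lipid transfer gene osbpl8 (-2.95 ± 0.16) and the Ran-binding protein gene ranbp3 (-2.7 ± 0.08). The ranbp3 level went from 76.6 ± 4.39 to 11.8 ± 0.609 CPM. Further falls were those of the nuclear receptor gene rora (-2.48 ± 0.28), the kinase gene dclk1 (ENSDARG00000104664, -2.44 ± 0.18), the cytochrome P450 gene cyp1c1 (-2.39 ± 0.57) and the complement gene c3b.1 (-2.15 ± 0.39). Of 21400 genes, 3330 rose and 3682 fell, 32.8% in all, and 1223 of them changed at least 2-fold. With library totals alone the split was 4306 up and 2888 down. The calls of cyp1c1 (adjusted p = 0.135 without replicate number 1) and smyhc1 (0.0807 without replicate number 2) were lost without a whole number, over a range of 3.88e-10 to 0.135 in the alternatives.

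Genes of the cytosolic ribosome and of the respiratory chain fell together after the knockdown in DMSO, while mitochondrially encoded mRNAs rose. Of 94 genes in the cytosolic ribosomal protein list, 57 fell and 4 rose (64 and 7 adjusted over the list alone), with a median of -0.21, as in rpl3 (-0.74 ± 0.06), rpl22l1 (-0.77 ± 0.07) and rpl10a (-0.54). The list test gave adjusted p = 5.98e-09, and adjusted p = 0.599 with an estimated correlation. That list also holds 12 genes that encode no ribosomal protein, kinases of the rps6k family and rps19bp1. Among the other 82 genes 57 fell and 1 rose, with a median of -0.22. Of 84 nuclear-encoded oxidative phosphorylation genes, 35 fell and 1 rose (37 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 2.17e-07; adjusted p = 0.599 with an estimated correlation). Examples were ndufa2 of complex I (-1.66 ± 0.17), atp5f1e of ATP synthase (-1.10 ± 0.10), uqcrfs1 of complex III (-0.83 ± 0.06) and cox7c of complex IV (-0.55 ± 0.06). Of 13 mitochondrially encoded mRNAs, 9 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.32, among them mt-nd4 (0.51 ± 0.06) and mt-atp6 (0.40 ± 0.05). That list had adjusted p = 7.24e-06, and adjusted p = 0.599 with an estimated correlation. Histone mRNAs, which are short, had a median of -0.26 in the same comparison, with 13 of 29 lower and 2 higher. Sm and LSm mRNAs had a median of -0.17, with 9 of 22 lower and 2 higher. The nuclear RNA malat1 took 0.30% ± 0.0366 (SD, n = 3) of counts in control DMSO and 0.415% ± 0.0219 in tif1g DMSO.

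Proliferation genes, nucleotide synthesis genes and markers of the outer embryo and yolk were also lower after the knockdown in DMSO. Of 34 cell cycle genes 23 fell and 0 rose (23 and 0 adjusted over the list alone), with a median of -0.29, including the topoisomerase gene top2a (-0.73 ± 0.07), the replication clamp gene pcna (-0.62 ± 0.06) and the helicase gene mcm5 (-0.54). The test gave adjusted p = 2.62e-06, and adjusted p = 0.599 with an estimated correlation. Of 30 pyrimidine genes 12 fell and 4 rose (12 and 4 adjusted over the list alone), with a median of -0.23 (adjusted p = 0.00809; adjusted p = 0.599 with an estimated correlation). The gene cad, which encodes the first enzymes of pyrimidine synthesis, fell by 0.92 ± 0.07, and the salvage kinase gene uck2 rose by 0.70 ± 0.07. Of 16 purine synthesis genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.21, such as atic (-0.41) and adssl (-0.35), at adjusted p = 0.00591, and adjusted p = 0.599 with an estimated correlation. Of 33 enveloping layer genes 19 fell and 3 rose (21 and 3 adjusted over the list alone), with a median of -0.26 (adjusted p = 3.2e-05; adjusted p = 0.599 with an estimated correlation). The keratin gene krt91 (-1.78 ± 0.17), anxa1b (-0.94 ± 0.07) and evpla (-0.77 ± 0.05) were among them. Of 34 yolk syncytial layer genes 18 fell and 3 rose (18 and 4 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.000235; adjusted p = 0.599 with an estimated correlation). These included the apolipoprotein genes apoc1 (-0.99 ± 0.10) and apobb.1 (-0.87 ± 0.07) and the nuclear receptor gene hnf4b (-0.70 ± 0.07). Of 38 genes that rise at the end of gastrulation 17 fell and 0 rose (19 and 0 adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00145; adjusted p = 0.599 with an estimated correlation). Among them were the eye field gene rx3 (-0.73 ± 0.10), the neuronal RNA-binding gene elavl3 (-0.69 ± 0.10), the neurogenic gene neurog1 (-0.58) and the myosin chaperone gene unc45b (-0.52 ± 0.05).

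Other lists did not pass the list test in DMSO, although single members did. Of 26 Nodal and TGF-beta targets 7 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.18, adjusted p = 0.0709, and 0.0454 with the replicate block, over a range of 0.00591 to 0.599 in the alternatives). They included the Nodal ligand gene ndr2 (1.07 ± 0.10), the endomesoderm gene mixl1 (0.71) and the matrix gene tgfbi (-1.25). Of 31 erythroid and heme genes 7 rose and 5 fell (7 and 5 adjusted over the list alone). The alpha globin gene hbae1.2 fell by 2.86 ± 0.53 and the erythroid factor gene nfe2 rose by 0.63 ± 0.12. The median of that list was -0.04 and its mean -0.14, while the test pointed up (adjusted p = 0.769). Of 20 hemangioblast, endothelial and myeloid genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; median -0.21, adjusted p = 0.519), with the vascular receptor genes kdrl at -0.79 ± 0.16 and tie1 at -1.05 ± 0.27 and the leukocyte gene lcp1 at -0.92. The tie1 call was lost without replicate number 2 (adjusted p = 0.0711) or 3, over a range of 0.00126 to 0.0711. Of 41 ribosome biogenesis genes 13 rose and 12 fell (13 and 14 adjusted over the list alone; median -0.02, adjusted p = 0.769), and of 75 mitochondrial ribosomal protein genes 4 rose and 15 fell (4 and 13 adjusted over the list alone; median -0.08, adjusted p = 0.0855).

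The remaining lists did not pass the list test in DMSO either. The TCA cycle list had a median of -0.14 (adjusted p = 0.0814), glycolysis 0.14 (0.661), coenzyme Q synthesis 0.08 (0.661), cholesterol synthesis 0.10 (0.768), the integrated stress response -0.02 (0.769) and heat shock -0.13 (0.128). Interferon genes had a median of 0.23 (adjusted p = 0.769), aryl hydrocarbon receptor targets -0.02 (0.769), immediate early genes 0.05 (0.335) and transcription elongation genes 0.03 (0.417). The hypoxia list had a median of 0.035 (adjusted p = 0.769), a mean of -0.001 and a test that pointed up. Among the members named by the rule, the hexokinase gene hk1 (-1.40 ± 0.11), the serine synthesis gene phgdh (-1.09 ± 0.07), the farnesyl diphosphate synthase gene fdps (-0.80 ± 0.08) and nqo1 (-0.71 ± 0.07) fell, and gapdh rose by 0.60. For stage and tissue, maternal transcripts had a median of 0.22 (adjusted p = 0.0855), blastula to early gastrula genes 0.08 (0.162), primordial germ cells 0.31 (0.49), endoderm 0.11 (0.378), paraxial mesoderm -0.09 (0.197) and lateral mesoderm -0.15 (0.197). Neural plate genes had a median of -0.08 (adjusted p = 0.643), neural crest -0.04 (0.335) and hatching gland -0.33 (0.335). In 3 further lists the signs differed. BMP targets had a median of -0.01, a mean of 0.03 and a test pointing up (adjusted p = 0.627). Epidermal ectoderm had 0.07, -0.10 and a test pointing up (0.768), and axial mesoderm 0.02, -0.11 and a test pointing down (0.769). Members of these lists that fell were the neural crest factor gene foxd3 (-0.74), the heart field gene tbx20 (-1.19 ± 0.26) and the hatching enzyme gene he1.2 (-1.23 ± 0.24), and the oocyte gene zar1 rose by 0.94 ± 0.22.

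With leflunomide present, the knockdown changed many of the same transcripts as in DMSO. The gene bmf2 rose by 4.37 ± 0.41, vstm2b by 3.37 ± 0.28, avd by 3.28 ± 0.21, ly75 by 3.05 ± 0.08 and the muscarinic receptor gene chrm5 (ENSDARG00000069598) by 2.79 ± 0.28. The largest falls were those of ube2o (ENSDARG00000100674, -4.08 ± 0.20), osbpl8 (-3.13 ± 0.16), ranbp3 (-2.66 ± 0.07), smyhc1 (-2.47 ± 0.67) and the midbrain homeobox gene en2 (ENSDARG00000026599, -2.35 ± 0.24). In all, 2564 genes rose and 2530 fell, 23.8% of those tested. Between the knockdown in DMSO and in leflunomide, 1694 genes were up in both, with 399 expected for independent calls, 1940 were down in both, with 435 expected, and 1 was up in DMSO and down in leflunomide. Of the 7012 genes called in DMSO, 93.9% moved in the same direction in leflunomide. Across 14979 genes, which are not independent replicates, the knockdown effects of the arms correlated at r = 0.836 and rho = 0.787. The smyhc1 call (adjusted p = 0.0287) was lost without control_leflunomide replicate 1 (0.0852) or 2 (0.0637) and without tif1g_leflunomide replicate 1 (0.0921) or 3 (0.0931), with a range of 0.00119 to 0.112 over the alternatives.

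Ribosome biogenesis genes and genes of the early gastrula rose after the knockdown in leflunomide. Of 41 ribosome biogenesis genes 19 rose and 3 fell (21 and 4 adjusted over the list alone; median 0.16, adjusted p = 6.83e-05, and adjusted p = 0.725 with an estimated correlation). The polymerase subunit gene polr1c (1.09 ± 0.07), the helicase gene ddx18 (0.61 ± 0.05) and wdr43 (0.52) rose. Of 35 blastula to early gastrula genes 12 rose and 5 fell (15 and 5 adjusted over the list alone; median 0.23, adjusted p = 0.00367, and adjusted p = 0.725 with an estimated correlation). The apelin receptor gene aplnrb was among them (0.94 ± 0.10). Of 29 BMP targets 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.0214, and adjusted p = 0.725 with an estimated correlation). The ventralising gene vox rose by 0.24, a call lost without replicate number 1 (adjusted p = 0.056, range 0.000125 to 0.056), and the ligand gene bmp7a by 0.46 ± 0.08. Cell cycle genes were lower as in DMSO, with 13 of 34 down and 0 up (13 and 0 adjusted over the list alone; median -0.15, adjusted p = 0.00113, and adjusted p = 0.725 with an estimated correlation). Genes that rise at the end of gastrulation fell too, 9 of 38 down and 4 up (12 and 4 adjusted over the list alone; median -0.28, adjusted p = 0.0328, and adjusted p = 0.725 with an estimated correlation). The lists of cytosolic ribosomal proteins (median 0.05, adjusted p = 0.0814) and oxidative phosphorylation (0.07, adjusted p = 0.54) did not pass in leflunomide. Histone mRNAs had a median of 0.13, with 8 of 29 higher and 2 lower, and the summed level of the 146 silent genes described below was 13.8 ± 2.31 CPM in control leflunomide and 8.51 ± 0.638 in tif1g leflunomide. With the replicate block 6 further lists passed, namely maternal transcripts (adjusted p = 0.0285), Nodal targets (0.0247), mitochondrially encoded mRNAs (0.0175), pyrimidine synthesis (0.0247), endoderm (0.0291) and enveloping layer (0.0285), and over all alternatives their adjusted p ran from 0.000484 to 0.735. The BMP call was lost without control_leflunomide replicate 1 (adjusted p = 0.084) or 2 (0.0554) or tif1g_leflunomide replicate 3 (0.0958), and the end-of-gastrulation call without control_leflunomide replicate 1 (0.084) or tif1g_leflunomide replicate 3 (0.0831), with a range of 0.000782 to 0.725 over the alternatives of both.

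Leflunomide in control embryos, the comparison that asks what the drug does without the knockdown, raised the lipid synthesis genes mid1ip1a and elovl3 and lowered the endoderm gene sox32. The lipogenesis regulator gene mid1ip1a rose by 1.72 ± 0.18 on the log2 scale (40.2 ± 4.0 to 132 ± 23.4 CPM, 3.29-fold, adjusted p = 0.00023) and the fatty acid elongase gene elovl3 by 1.28 ± 0.29 (20.5 to 49.8 CPM). Other large rises were those of pcdh1g22 (1.41 ± 0.30), the glutamate decarboxylase gene gad3 (1.40 ± 0.29), the transporter gene slc6a18 (1.37 ± 0.28), bsk146 (1.24 ± 0.25) and the synaptic gene insyn2a (ENSDARG00000107296, 1.23 ± 0.17). The tendon factor gene scx rose by 1.22 ± 0.18, the presynaptic scaffold gene pclo by 1.21 ± 0.21 and the sodium channel gene scn8a (ENSDARG00000018032) by 1.2 ± 0.26. The largest falls were those of the protease gene adamts15 (ENSDARG00000033544, -1.25 ± 0.30), the purine nucleoside phosphorylase gene pnp4a (-1.07 ± 0.29), the endoderm factor gene sox32 (-1.07 ± 0.26, 12.5 ± 3.86 to 5.96 ± 1.63 CPM) and ccndx (-1.05 ± 0.36). Other falls were those of the cysteine synthesis gene cth (ENSDARG00000032206, -1.01 ± 0.27), prelid3a (-0.88 ± 0.21), pcbd1 (-0.86 ± 0.28) and the mitochondrial gene chchd10 (-0.82 ± 0.21). The cytochrome P450 genes cyp27c1 (-0.85 ± 0.19) and cyp2p6 (-0.85 ± 0.28) fell as well. In all 1899 genes rose and 2796 fell, 21.9% of those tested, with a median size of 0.38, and 288 changed at least 2-fold, 271 up and 17 down. With library totals alone the median of all genes moved from 0.02 to 0.16 and the split was 3538 up and 1220 down. The count fell to 3116 without control_leflunomide replicate 2. Calls were also lost for sox32 without control_leflunomide replicate 2 (adjusted p = 0.0525), elovl3 without control_DMSO replicate 1 (0.0549), chchd10 without control_leflunomide replicate 1 (0.0527), cth without control_DMSO replicate 2 (0.0746), and pnp4a without control_DMSO replicate 2 or control_leflunomide replicate 1 or 2 (up to 0.0651). The genes ccndx (up to 0.248 without control_DMSO replicate 2), cyp2p6 (up to 0.168 without control_leflunomide replicate 2) and pcbd1 (up to 0.154 without control_leflunomide replicate 2) each lost theirs in 4 of the 6 omissions, and over all alternatives the adjusted p of these 8 genes ran from 3.15e-07 to 0.248. Without a whole replicate number prelid3a (adjusted p up to 0.124), gad3 (0.119), adamts15 (0.0765), bsk146 (0.0635) and scn8a (0.059) lost their calls too, over a range of 9.12e-06 to 0.124.

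Ribosomal genes and nuclear genes of the mitochondrion fell together with leflunomide in control embryos. Of 41 ribosome biogenesis genes 35 fell and 0 rose (37 and 0 adjusted over the list alone; median -0.36, adjusted p = 4.61e-27, and adjusted p = 0.073 with an estimated correlation). Falls included those of wdr12 (-0.52 ± 0.06), utp6 (-0.48 ± 0.05) and the box C/D protein gene nop58 (-0.44). Of 94 genes in the cytosolic ribosomal protein list 77 fell and 0 rose (80 and 0 adjusted over the list alone; median -0.28, adjusted p = 2.19e-23, and adjusted p = 0.275 with an estimated correlation). The large subunit gene rpl30 fell by 0.37 ± 0.06, and the related rpl7l1 changed by -0.62 ± 0.05. Of 84 oxidative phosphorylation genes 63 fell and 0 rose (72 and 1 adjusted over the list alone; median -0.41, adjusted p = 6.18e-25, and adjusted p = 0.134 with an estimated correlation). Complex III, complex IV and ATP synthase were represented by uqcrq (-0.73 ± 0.09), cox7c (-0.64 ± 0.06) and atp5f1c (-0.56 ± 0.07). Of 75 mitochondrial ribosomal protein genes 55 fell and 0 rose (59 and 0 adjusted over the list alone; median -0.37, adjusted p = 7.53e-20, and adjusted p = 0.073 with an estimated correlation). The gene mrpl44 was among them (-0.63 ± 0.08). Of 13 mitochondrially encoded mRNAs 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.18, adjusted p = 0.000871, and adjusted p = 0.359 with an estimated correlation). The complex I transcript mt-nd4 rose by 0.34 ± 0.06. In the same comparison histone mRNAs had a median of -0.50, with 22 of 29 lower, and the nuclear RNA malat1 took 0.30% ± 0.0366 (SD, n = 3) of counts in control DMSO and 0.538% ± 0.0327 in control leflunomide. Reads on 146 genes silent at this stage summed to 9.25 ± 1.77 CPM in control DMSO, 13.8 ± 2.31 in control leflunomide, 8.42 ± 1.14 in tif1g DMSO and 8.51 ± 0.638 in tif1g leflunomide.

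Chaperone, nucleotide and cell cycle genes fell with leflunomide in control embryos as well. Of 24 heat shock and unfolded protein response genes 14 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.32, adjusted p = 1.66e-07, and adjusted p = 0.134 with an estimated correlation). Of the 4 members with the smallest p, hspe1 (-0.82 ± 0.10), hspd1 (-0.64 ± 0.07) and hspa9 (-0.45) encode chaperones of the mitochondrial matrix, and hspa8 (ENSDARG00000068992, -0.28 ± 0.05) a constitutive cytosolic one. Of 16 purine synthesis genes 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.28, adjusted p = 1.98e-08, and adjusted p = 0.073 with an estimated correlation). The gene paics changed by -0.47 and gmps by -0.40 ± 0.05. Of 23 TCA cycle genes 14 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.29, adjusted p = 3.41e-07, and adjusted p = 0.073 with an estimated correlation). The citrate synthase gene cs (-0.36) was among them. Of 34 cell cycle genes 14 fell and 0 rose (16 and 0 adjusted over the list alone; median -0.22, adjusted p = 5.84e-06, and adjusted p = 0.323 with an estimated correlation). The replication gene pcna (-0.42) and the cyclin gene ccnb1 (-0.40) fell. Of 30 pyrimidine genes 8 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.16, adjusted p = 0.0577, and 0.0258 with the replicate block, over a range of 0.00881 to 0.323), among them umps, which encodes the enzyme after dhodh in the pathway (-0.48 ± 0.06), and uck2 (-0.52 ± 0.07). With the replicate block 3 further lists passed, the integrated stress response (adjusted p = 0.0581 to 0.0415), BMP targets (0.0607 to 0.0339) and glycolysis (0.0674 to 0.0449). Each also passed with at least 1 other alternative, and over all alternatives they ran from 1.3e-05 to 0.622.

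Among tissue and stage lists, yolk syncytial layer genes fell in 16 of 34 and rose in 1 (19 and 1 adjusted over the list alone; median -0.33, adjusted p = 2.49e-05, and adjusted p = 0.275 with an estimated correlation). The lipid transfer gene mttp was one of them (-0.48 ± 0.07). Blastula to early gastrula genes fell in 9 of 35 and rose in 1 (10 and 1 adjusted over the list alone; median -0.19, adjusted p = 0.000245, and adjusted p = 0.323 with an estimated correlation). The ventralising gene vox fell by 0.33. Endoderm genes fell in 8 of 16 (8 down and 1 up adjusted over the list alone; median -0.25, adjusted p = 0.00176, and adjusted p = 0.275 with an estimated correlation). The genes sox32 and foxa3 (-0.30) were among them. Paraxial mesoderm genes fell in 10 of 31 (10 adjusted over the list alone; median -0.18, adjusted p = 0.0017, and adjusted p = 0.275 with an estimated correlation). Enveloping layer genes fell in 10 of 33 and rose in 1 (12 and 2 adjusted over the list alone; median -0.20, adjusted p = 0.0017, and adjusted p = 0.311 with an estimated correlation). The keratin gene krt8 fell by 0.29. Erythroid and heme genes fell in 7 of 31 (7 adjusted over the list alone; median -0.17, adjusted p = 0.0485, and adjusted p = 0.275 with an estimated correlation). These included the heme synthesis gene alas1 (-0.29) and the transferrin receptor gene tfr1b (-0.47). Those calls were lost without replicate number 1 for alas1 (adjusted p = 0.128) and number 2 for tfr1b (0.0959), and with library totals alone for alas1 (0.12), over a range of 5.49e-07 to 0.128. Maternal transcripts fell in 2 of 27 (2 adjusted over the list alone; median -0.24, adjusted p = 0.0231, and adjusted p = 0.323 with an estimated correlation). Transcription elongation genes fell in 9 of 31 and rose in 2 (13 and 2 adjusted over the list alone; median -0.08, adjusted p = 0.0338, and adjusted p = 0.311 with an estimated correlation). With library totals alone the list median was 0.05, below the median of all genes, 0.16. The maternal call was lost without control_leflunomide replicate 1 (adjusted p = 0.0891), the elongation call without control_DMSO replicate 2 (0.104), and the erythroid and heme call without control_DMSO replicate 1 (0.156) or control_leflunomide replicate 2 (0.0762) or 3 (0.0591), over a range of 0.00348 to 0.323 for the 3 lists. The list of aryl hydrocarbon receptor targets (median -0.14, adjusted p = 0.835) did not pass.

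**Figure D2:**
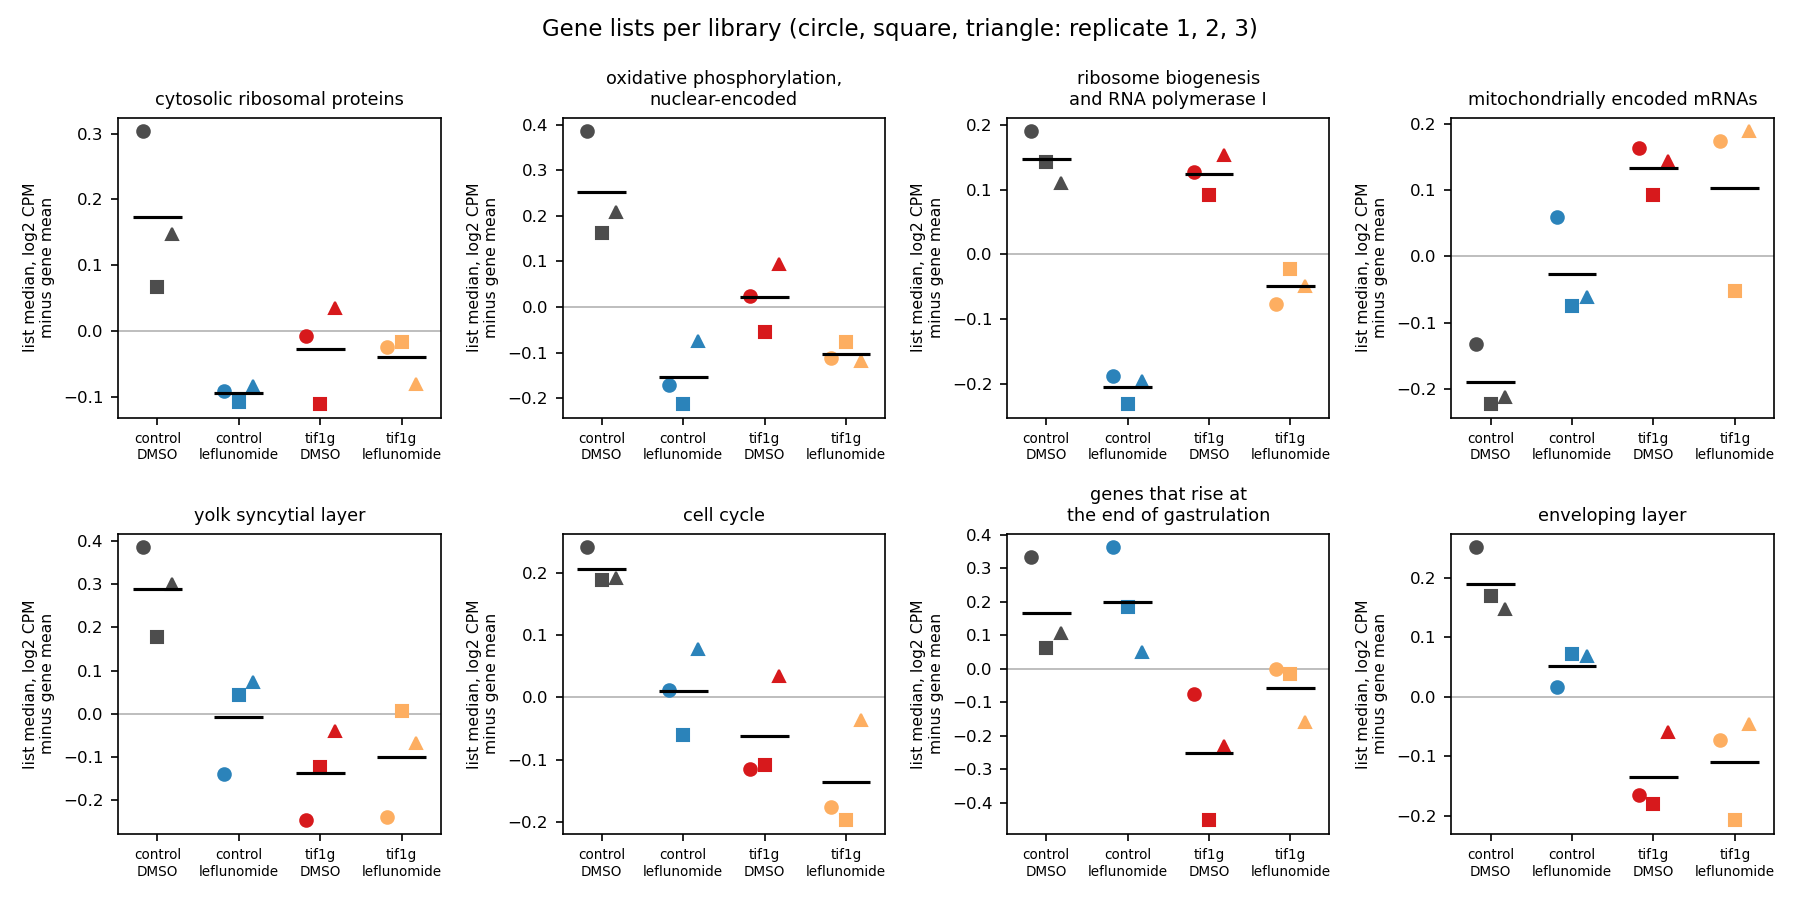
Median over the genes of 8 lists of log2 CPM minus the gene's mean over all libraries (vertical axes), with 1 point per library by group and replicate number and a bar at the group mean. Ribosome biogenesis and oxidative phosphorylation lie lower in control leflunomide than in control DMSO, with list medians of the change of -0.36 and -0.41.

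Leflunomide in tif1g embryos, which asks whether the drug acts in the same way after the knockdown, changed fewer genes. The gene mid1ip1a rose by 1.26 ± 0.18 (adjusted p = 0.0315, 42.1 to 101 ± 24.6 CPM), the fatty acid synthesis gene hsd17b12 by 0.73 ± 0.10 (153 to 255 CPM), elavl3 by 0.64 ± 0.10 and the transcription factor gene klf7 (ENSDARG00000043821) by 0.75 ± 0.14. Further rises were those of the zinc finger gene znf385a (1.00 ± 0.23), fam168a (0.84 ± 0.14), ftr86 (0.67), the sialyltransferase gene st8sia6 (0.60), the protease gene adamts7 (0.59) and rassf2 (0.59). The neural factor gene zic5 fell most (-0.77 ± 0.16, adjusted p = 0.0428). It was followed by bcl2l13 (-0.55), the mitochondrial ribosomal gene mrpl28 (-0.48 ± 0.09), the ATP synthase assembly gene atpaf2 (-0.48) and the snoRNP assembly gene naf1 (-0.46). Smaller falls were those of the chaperone gene hspa4 (ENSDARG00000004754, -0.45 ± 0.06), the RNA exosome gene exosc6 (-0.44), fam136a (-0.42), ttbk2b (-0.39) and the Integrator gene ints6 (-0.39 ± 0.07). In all 41 genes rose and 91 fell, with a median size of 0.32. By comparison 1518 passed with the replicate block (578 up, 940 down), 652 with DESeq2 and 56 with limma voom, and with library totals alone 51 rose and 15 fell. The count fell with each of the 6 omissions of a library. It was 8, 2 and 0 without tif1g_DMSO replicate 1, 2 or 3 and 0, 0 and 27 without tif1g_leflunomide replicate 1, 2 or 3. Each of the 20 genes named here by size lost its call in at least 1 of these 6 omissions, at adjusted p up to 0.232. These omissions were fitted without the replicate block, and the 1518 genes called with the block held all 132.

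As a group, ribosome biogenesis genes were again lower with leflunomide in tif1g embryos. Of 41 genes 4 fell and 0 rose (30 and 0 adjusted over the list alone; median -0.17, adjusted p = 5.95e-26, and adjusted p = 0.114 with an estimated correlation). The 4 were utp4 (-0.33 ± 0.06), wdr3 (-0.23), nop56 (-0.22) and ncl (-0.22). Of 75 mitochondrial ribosomal protein genes 1 fell (11 adjusted over the list alone; median -0.18, adjusted p = 5.52e-15, and adjusted p = 0.239 with an estimated correlation). Of 84 oxidative phosphorylation genes 0 were called by edgeR (7 down adjusted over the list alone; median -0.14, adjusted p = 6.09e-10, and adjusted p = 0.384 with an estimated correlation). Purine synthesis had a median of -0.13 (adjusted p = 0.000162; adjusted p = 0.267 with an estimated correlation). Its gene gmps fell by 0.32 ± 0.05. Heat shock genes had -0.14 (adjusted p = 0.000184; adjusted p = 0.296 with an estimated correlation), with hspd1 at -0.32 ± 0.07. TCA cycle genes had -0.11 (adjusted p = 0.00161; adjusted p = 0.287 with an estimated correlation), with mdh2 at -0.29 ± 0.06. Endoderm genes had a median of -0.19 (adjusted p = 0.000439; adjusted p = 0.287 with an estimated correlation), maternal transcripts -0.22 (adjusted p = 0.000755; adjusted p = 0.287 with an estimated correlation) and blastula genes -0.12 (adjusted p = 0.000755; adjusted p = 0.44 with an estimated correlation). Transcription elongation genes had -0.09 (adjusted p = 0.00317; adjusted p = 0.287 with an estimated correlation), with tcea1 at -0.26 ± 0.05. Cell cycle genes had -0.08 (adjusted p = 0.00161; adjusted p = 0.491 with an estimated correlation). Higher were genes that rise at the end of gastrulation (median 0.20, adjusted p = 0.00303; adjusted p = 0.44 with an estimated correlation) and immediate early genes (0.10, adjusted p = 0.0423; adjusted p = 0.477 with an estimated correlation). Histone mRNAs had a median of -0.14 and Sm and LSm mRNAs of -0.10, and malat1 took 0.415% ± 0.0219 (SD, n = 3) of counts in tif1g DMSO and 0.506% ± 0.0384 in tif1g leflunomide. Cytosolic ribosomal proteins had a median of -0.01 (adjusted p = 0.571, range 0.00182 to 0.933, passing without tif1g_DMSO replicate 2), and Nodal targets passed with the replicate block alone (adjusted p = 0.156 to 0.0488, over a range of 0.0488 to 0.44). Calls were lost without tif1g_DMSO replicate 2 for end-of-gastrulation genes (adjusted p = 0.154) and immediate early genes (0.426), without tif1g_DMSO replicate 3 for cell cycle (0.273) and immediate early genes (0.0751), and without tif1g_leflunomide replicate 2 for cell cycle (0.0823) or replicate 1 for immediate early genes (0.239), over a range of 2.06e-06 to 0.491 for these 3 lists.

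**Figure D3:**
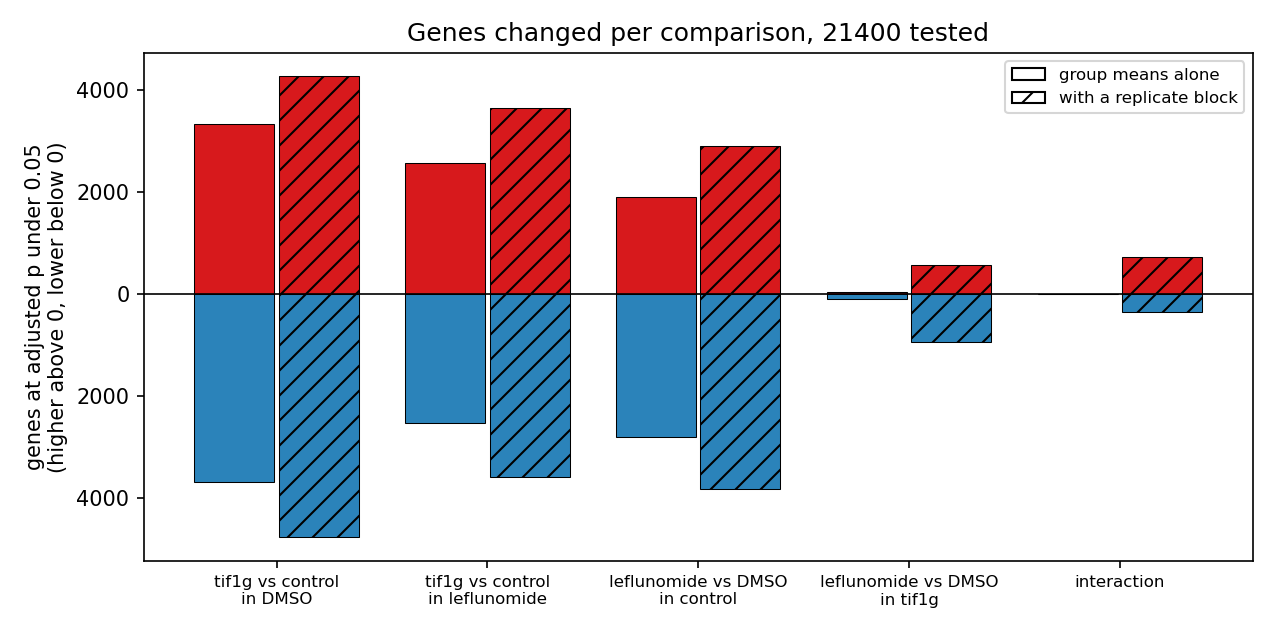
Number of genes at an adjusted p under 0.05 (vertical axis) in 5 comparisons, those higher above 0 in red and those lower below 0 in blue, with hatched bars for the fit with the replicate block. Leflunomide in tif1g embryos gave 41 genes higher and 91 lower, and 578 and 940 with the replicate block.

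Most genes moved with leflunomide in the same direction in both kinds of embryo, by less in the libraries labelled tif1g. Of the 4695 genes called in control embryos 91.2% moved in the same direction in tif1g embryos, and of the 132 called in tif1g embryos 126 were called in both, 38 up with 3.64 expected and 88 down with 11.9 expected. Across 14979 genes, which are not independent replicates, the leflunomide effects correlated at r = 0.580 and rho = 0.611 with a slope of 0.371, against a slope of 0.736 for the knockdown effects. Noise in the first effect lowers such a slope, and more so where effects are small, so the slopes alone do not compare what was carried over. In the cross-fitted measure, genes selected for the knockdown in DMSO changed by a median of 0.475 ± 0.0579 in the number left out and by 0.337 ± 0.0217 in leflunomide, a share of 71.5% ± 9.14 (SD, n = 3 numbers). Genes selected for leflunomide in control embryos changed by 0.367 ± 0.0832 and by 0.146 ± 0.0371 after the knockdown, a share of 42.2% ± 18.3. With 3 numbers no exact paired test of these differences can give a two-sided p below 0.25. Both shares are taken of effects measured against the control DMSO libraries.

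**Figure D4:**
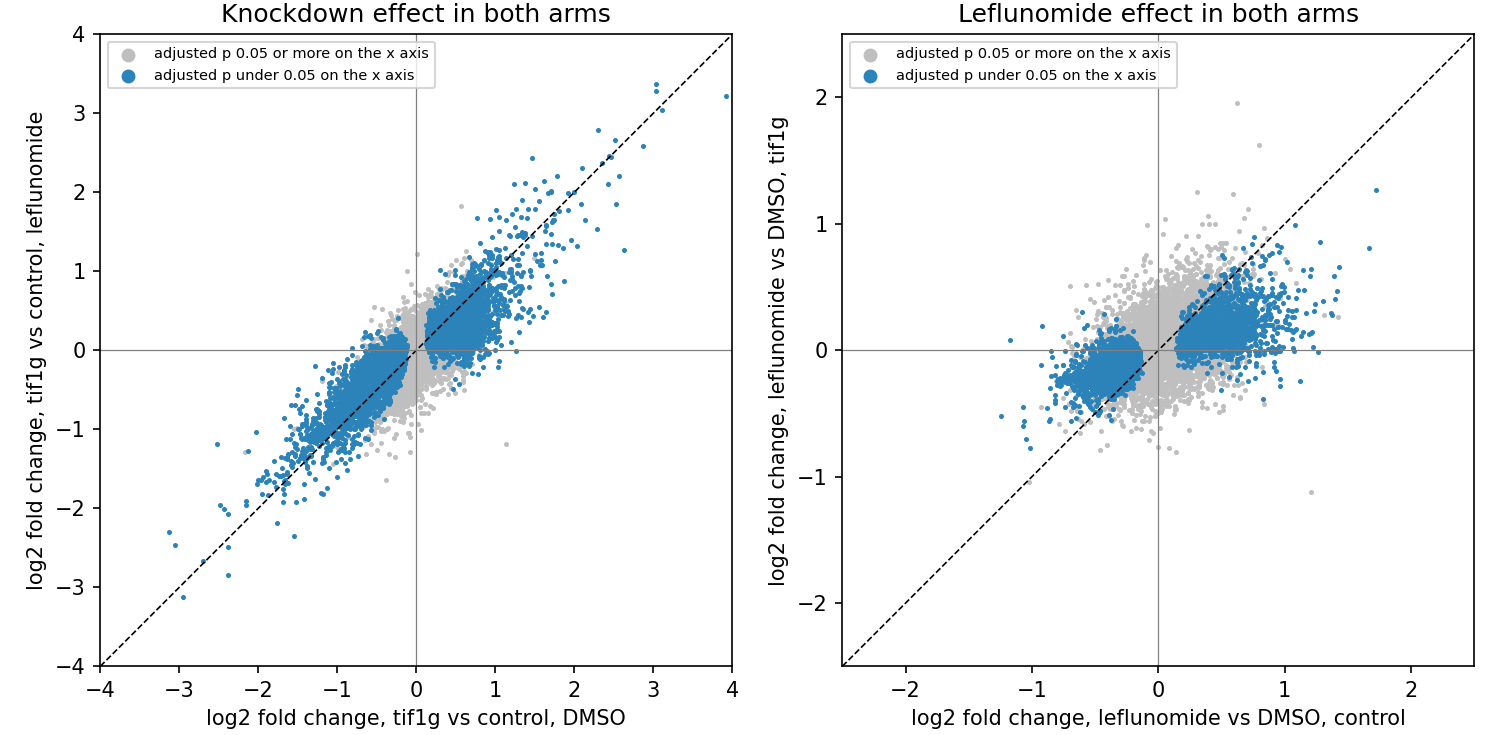
Log2 fold change of each of 14992 genes with a mean log2 CPM of at least 1, with the knockdown effect in DMSO against that in leflunomide on the left, and the leflunomide effect in control against that in tif1g embryos on the right. Blue points were called on the horizontal axis, the dashed line marks equal effects, 4 genes lie outside the left axes, and the slopes over 14979 of the genes were 0.736 and 0.371.

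The interaction, which tests whether the effect of leflunomide differed between the morpholinos, passed for gene groups. By edgeR's test it passed for 0 single genes without the replicate block and for 1067 with it. Cytosolic ribosomal protein genes had a median interaction of 0.26 (adjusted p = 1.69e-32; adjusted p = 0.204 with an estimated correlation), with a fall in control embryos and a median near 0 in tif1g embryos. By edgeR 0 of its 94 genes were called, and 70 rose adjusted over the list alone. Oxidative phosphorylation genes had 0.27 (adjusted p = 3.16e-19; adjusted p = 0.204 with an estimated correlation), ribosome biogenesis genes 0.17 (adjusted p = 1.1e-15; adjusted p = 0.204 with an estimated correlation) and mitochondrially encoded mRNAs -0.20 (adjusted p = 3.08e-07; adjusted p = 0.22 with an estimated correlation). Yolk syncytial layer genes had 0.30 (adjusted p = 3.08e-07; adjusted p = 0.206 with an estimated correlation). The value for hnf4b was 0.56 ± 0.09 (adjusted p = 0.0985, and 0.000882 with the replicate block, over a range of 0.000137 to 0.785). In all 16 lists passed, 15 up and 1 down, and histone mRNAs had a median of 0.37. The cytosolic ribosomal protein list took 3.69% ± 0.258 (SD, n = 3) of counts in control DMSO. It took 3.35% ± 0.0113 in control leflunomide, 3.27% ± 0.126 in tif1g DMSO and 3.35% ± 0.109 in tif1g leflunomide. Control DMSO, the highest of the 4 groups, enters the knockdown in DMSO, leflunomide in control embryos, the interaction and tif1g leflunomide against control DMSO. A shift of its libraries alone cannot be told apart from an interaction. The interaction of trim33 was 0.03 ± 0.08 (adjusted p = 0.938) and that of dhodh 0.28 ± 0.14 (adjusted p = 0.457). Among all genes 0 passed edgeR's quasi-likelihood test, with 2560 at an unadjusted p under 0.05, 364 called by DESeq2 (276 up, 88 down) and 0 by limma voom. Of the 16 list calls, cell cycle was lost without tif1g_leflunomide replicate 3 (adjusted p = 0.112), and end-of-gastrulation genes, BMP targets and pyrimidine synthesis were lost in 7, 5 and 5 of the 12 omissions of a library, up to adjusted p = 0.333, 0.17 and 0.143, and over all alternatives these 4 lists ran from 5.79e-06 to 0.627. Glycolysis (adjusted p = 0.0756 to 0.0326), the hatching gland (0.0984 to 0.0473) and blastula genes (0.0984 to 0.0377) passed with the replicate block, over a range of 0.00414 to 0.728. Glycolysis passed with fry as well, and blastula genes in 4 of the 12 omissions of a library. With the replicate block edgeR called 1067, of which 721 were up and 346 down.

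Embryos with both the tif1g morpholino and leflunomide had the highest number of called genes against control embryos in DMSO. The gene bmf2 rose by 5.68, ly6pge by 3.06, vstm2b by 2.96, avd by 2.93 and ly75 by 2.93. Lower were ube2o (ENSDARG00000100674, -3.75 ± 0.20), osbpl8 (-3.08), ranbp3 (-2.64), the microtubule gene map1b (-2.44 ± 0.44) and ndufa2 (-2.16 ± 0.18). Oxidative phosphorylation genes had a median of -0.35 (adjusted p = 6.2e-13; adjusted p = 0.458 with an estimated correlation), cytosolic ribosomal proteins -0.21 (adjusted p = 2.56e-09; adjusted p = 0.56 with an estimated correlation), cell cycle genes -0.33 (adjusted p = 9.28e-09; adjusted p = 0.458 with an estimated correlation) and mitochondrial ribosomal proteins -0.24 (adjusted p = 4.54e-08; adjusted p = 0.458 with an estimated correlation). Histone mRNAs had a median of -0.41, with 17 of 29 lower, and Sm and LSm mRNAs of -0.33, with 13 of 22 lower, and malat1 took 0.30% ± 0.0366 (SD, n = 3) and 0.506% ± 0.0384 of counts. Pyrimidine genes fell in 14 of 30 and rose in 6 (15 and 6 adjusted over the list alone; median -0.30, adjusted p = 0.00795, and adjusted p = 0.458 with an estimated correlation). In all 13 lists and 7697 genes passed, 3694 up and 4003 down. With library totals alone the median of all genes moved from 0.01 to 0.13 and the split was 5322 up and 2644 down. The paraxial mesoderm list (adjusted p = 0.0572 to 0.0466) and that of genes that rise at the end of gastrulation (0.135 to 0.0466) passed with the replicate block, over a range of 0.00481 to 0.827. The paraxial list also passed with fry, without a filter and in 3 of the 6 omissions of a library. The map1b call was lost without replicate number 2 (adjusted p = 0.0533, range 3.01e-12 to 0.0533).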

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

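The tests of swapped libraries, normalisation, scaling factors, younger embryos, a single replicate number and a response to the morpholino, and the flips within pairs, were chosen after the results they address had been seen.

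In 16 of the 38 gene lists the effect of leflunomide differed between the morpholinos by the test of the difference itself, in 15 of them upward after the knockdown. The median interactions, on the log2 scale, were 0.257 for cytosolic ribosomal proteins, 0.268 for nuclear-encoded oxidative phosphorylation, 0.173 for ribosome biogenesis, 0.189 for mitochondrial ribosomal proteins and -0.204 for mitochondrially encoded mRNAs. They were 0.297 for the yolk syncytial layer, 0.19 for the enveloping layer, 0.185 for purine synthesis, 0.205 for heat shock and unfolded protein response genes, 0.137 for the TCA cycle and 0.254 for 1 further list. For cell cycle genes the value was 0.138, for paraxial mesoderm 0.145, for BMP targets 0.132, for pyrimidine synthesis and salvage 0.095 and for genes that rise at the end of gastrulation 0.159. With an estimated correlation the adjusted p of these 16 lists was 0.204 to 0.627.

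Among genes named by size or by choice, 4 moved in opposite directions in every replicate number of the groups compared. Leflunomide moved spns3 (interaction -0.686, adjusted p = 0.47), ube2o (ENSDARG00000100674, -0.601, adjusted p = 0.432) and dhodh (0.284, adjusted p = 0.457) in one direction in control embryos and the other in tif1g embryos, and the knockdown did so for zic5 (-0.858, adjusted p = 0.158) between DMSO and leflunomide. None of the 4 passed the test of the difference by edgeR without the replicate block, and with it zic5 did (adjusted p = 0.0194, range 0.0194 to 0.785 over the alternatives). These 4 came from 132 checks, where random signs in every number would give 4.125. Genes named by size already share a sign over the numbers of 1 comparison, so that value is a rough guide only. In tif1g embryos ube2o had 21 to 28 counts a library in DMSO and 18 to 25 in leflunomide. Its reversal there rests on few reads. Single outlying samples were not tested for in these groups of 3 libraries.

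The trim33 transcript was 5.08-fold higher in tif1g libraries in DMSO, opposite to the usual reading of a knockdown. A swap of single libraries is argued against by the levels, since the lowest tif1g library was 4.36 times the highest control library. An exchange of the morpholino labels of all libraries would give the same separation, so it cannot be told apart, and would turn the direction of every comparison of the morpholinos. Normalisation is argued against by the smallest log2 change over all alternatives, 2.31. Reads shared with a related gene are argued against by trim33l and trim24, whose highest change was 0.067. A morpholino that blocks translation may leave or stabilise its target RNA, or loss of the protein may raise it, and neither explanation was tested.

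In control embryos leflunomide lowered ribosome and mitochondrial protein mRNAs and raised malat1. The choice of scaling is argued against, since the higher of the medians of ribosome biogenesis and oxidative phosphorylation over the scalings was -0.223. The prediction for background reads held in control embryos. There the summed level of 146 silent genes was higher by 0.577 on the log2 scale in leflunomide than in DMSO. The sum itself was small, 9.25 ± 1.77 CPM in DMSO and 13.8 ± 2.31 in leflunomide, while malat1 went from 0.30% to 0.538% of counts. So small a sum argues against background reads as the cause of the lower lists or of the rise of malat1. Background reads stay open as a part of the changes of weakly expressed genes. In tif1g embryos the sum was 8.42 ± 1.14 CPM in DMSO and 8.51 ± 0.638 in leflunomide. Ribosome biogenesis genes were lower there as a group too, which argues against background reads in tif1g embryos. A loss of short transcripts in library preparation stays open too, because the higher of the medians of histone and of Sm and LSm mRNAs was -0.309. Transcript lengths were not analysed, and cell cycle genes fell in the same comparison, so these mRNAs do not isolate length. Ribosome biogenesis genes had a median of -0.356 and cytosolic ribosomal proteins -0.281, while mitochondrially encoded mRNAs had 0.177. An effect of the drug on growth remains a candidate explanation that these tests do not part from a loss of short transcripts. The interaction of the same lists is open in the same way. For the fall of ribosomal and respiratory chain mRNAs after the knockdown in DMSO and in tif1g leflunomide against control DMSO, where histone and Sm and LSm mRNAs were lower too, a loss of short transcripts stays open as well. The rise of ribosome biogenesis and early gastrula genes after the knockdown in leflunomide is measured against the same control leflunomide libraries and stays open in the same way.

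Genes that rise at the end of gastrulation were lower in tif1g libraries in both arms. A single replicate number is argued against, since the difference of the list median was below 0 in each number and arm, the highest being -0.201. Younger tif1g embryos at harvest could account for it and cannot be told apart, because the early lists were not called in both arms (highest adjusted p = 0.162) and neither was lower. A response to the morpholino itself could too, and stays open because only 1 tif1g morpholino was used. An effect of trim33 on the timing of differentiation is untested. Maternal transcripts and blastula to early gastrula genes were lower with leflunomide in both kinds of embryo, by camera at its preset correlation. Whether embryos in leflunomide and in DMSO differed in stage at harvest was not tested.

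Other splits of the same libraries were compared with the real groups. For the knockdown in DMSO, the real split gave 7012 genes and the highest of the others 0, and for the knockdown in leflunomide 5094 and 0. Leflunomide in control embryos gave 4695 and 0, leflunomide in tif1g embryos 132 and 0, and tif1g leflunomide against control DMSO 7697 and 0. In each of these 5 comparisons 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For the interaction the real count was 0, which any split reaches, so that all 100 of 100 splits gave as many and the count says nothing about chance. There 6 other splits called genes, up to 3199, and up to 1279 among the 16 that part all pairs, which points to the structure of the groups. With the replicate block, 6 of 32 flips of the treatments within pairs gave at least the real count of 1067, up to 7065. All 8 flips that left the control pairs in place called genes and 0 of the other 24 did, so the flips carry the leflunomide effect of the control pairs, do not isolate the interaction and leave chance open.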

How the results depend on the processing

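Library totals alone, omission of a whole replicate number, omission of libraries in the list tests, and the measures of leflunomide carried into tif1g embryos were tested after the data had been seen. Library totals alone shift all genes together. For leflunomide in control embryos the median of all genes moved from 0.024 to 0.156 and that of the transcription elongation list from -0.083 to 0.05, which stayed below it. The split of called genes there turned from 1899 up and 2796 down to 3538 up and 1220 down, and the balance also turned for the knockdown in DMSO and in leflunomide, leflunomide in tif1g embryos, and tif1g leflunomide against control DMSO. Of the values of named genes under the alternatives 16384 kept their side of the threshold, 884 lost their call and 295 gained one. For the gene lists these numbers were 2263, 137 and 108, and of the counts and effect sizes that answer the comparisons 161 stayed within their limits and 48 did not. The cause of these shifts was not tested, except that fewer libraries or a fold minimum leave fewer calls by construction. Depth was a small limit for abundant genes, where the spread between replicates exceeded counting error several times. For weak genes it was a limit, since gata1a had 3 to 14 counts a library and tal1 had 5 to 10 in tif1g DMSO.

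A minimum of 2-fold left 1223 genes for the knockdown in DMSO, 850 for the knockdown in leflunomide, 288 for leflunomide in control embryos, 1 for leflunomide in tif1g embryos and 1324 for tif1g leflunomide against control DMSO. Leflunomide in tif1g embryos gave 132 genes, and 66 with library totals alone, 652 with DESeq2, 56 with limma voom, 50 without the robust option, 1518 with the replicate block and 41 from the compared groups alone. The interaction gave 0 genes, and 3 with library totals alone, 364 with DESeq2, 1 without a filter and 1067 with the replicate block. The replicate block moved no other gene count by more than 1.5 times.

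Without 1 library the counts ran from 5480 to 6616 for the knockdown in DMSO, 3913 to 4300 in leflunomide, 3116 (without control_leflunomide replicate 2) to 4248 for leflunomide in control embryos and 6435 to 7073 for tif1g leflunomide against control DMSO. For leflunomide in tif1g embryos they ran from 0 (without tif1g_DMSO replicate 3, tif1g_leflunomide replicate 1 or tif1g_leflunomide replicate 2) to 27 (without tif1g_leflunomide replicate 3), with 8 and 2 without tif1g_DMSO replicates 1 and 2. For the interaction edgeR gave 0 in each of the 12 omissions. Without a whole replicate number the ranges were 4716 to 5305, 3002 to 3401 (3096 without replicate 2 and 3002 without replicate 3), 2118 to 3393 (2403 without replicate 1 and 2118 without replicate 2), 0 to 2 and 5340 to 5749 in the same order, and 0 for the interaction.

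With an estimated correlation 0 lists were called in each of the 6 comparisons. With fry 23 lists passed for the knockdown in DMSO, 13 for the knockdown in leflunomide, 4 for leflunomide in tif1g embryos and 5 for the interaction. In that order these held 9 of the 9, 3 of the 6, 3 of the 14 and 4 of the 16 lists that camera called, in the same direction. Without a filter 15 and 11 lists passed for the knockdown in DMSO and in leflunomide. The replicate block gave 12 lists for the knockdown in leflunomide, and omission of 1 library gave 5 to 10 there, 10 being without control_leflunomide replicate 3.

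The knockdown effect carried into leflunomide had medians of 1.12 and 0.95 with genes of at least 2-fold, and 0.31 in leflunomide with genes selected on all 6 libraries. The leflunomide effect carried into tif1g embryos had medians of 0.72 and 0.25 with genes of at least 2-fold. Without 1 replicate number the medians were 0.45 to 0.51 and 0.33 to 0.35 for the knockdown, and 0.34 to 0.41 and 0.13 to 0.17 for leflunomide.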

Other observations

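The genes elavl3 and crestin rose with leflunomide in control embryos, where the lists of neural plate (median -0.02, adjusted p = 0.906) and neural crest genes (0.00, adjusted p = 0.586) did not pass. The knockdown lowered elavl3 in both arms and crestin in leflunomide. The elavl3 transcript, which encodes a neuronal RNA-binding protein, stood at 14.8 CPM in control DMSO, 22.2 in control leflunomide, 9.16 in tif1g DMSO and 14.2 in tif1g leflunomide. It rose with leflunomide by 0.58 ± 0.10 in control embryos (adjusted p = 0.00033, edgeR's quasi-likelihood test, n = 3) and fell with the knockdown by 0.69 ± 0.10 in DMSO (adjusted p = 3.99e-05) and by 0.64 in leflunomide (adjusted p = 9.03e-05). The neural crest transcript crestin rose with leflunomide in control embryos by 0.69 ± 0.12 (33.7 to 54.2 CPM, adjusted p = 0.00114) and fell with the knockdown in leflunomide by 0.76 ± 0.12 (adjusted p = 0.000386), while with the knockdown in DMSO its change was -0.32 (33.7 to 27.0 CPM, adjusted p = 0.0626, and 0.0043 with the replicate block). Its interaction was -0.44 ± 0.17 (adjusted p = 0.312, and 0.036 with the replicate block, over a range of 0.036 to 0.897 in the alternatives). The eye field gene rx3 stood at 56.7 and 46.4 CPM in control DMSO and leflunomide and at 34.2 and 30.1 in tif1g embryos. It fell with the knockdown in DMSO by 0.73 ± 0.10 (adjusted p = 3.63e-05) and in leflunomide by 0.62 ± 0.10 (adjusted p = 0.000272).

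The lipid regulator gene srebf1 rose with leflunomide in control embryos by 0.90 ± 0.17 (4.22 to 7.86 CPM, adjusted p = 0.00104) and with the knockdown in DMSO by 0.69 ± 0.17 (adjusted p = 0.00482), a call lost without replicate number 2 (adjusted p = 0.15, range 0.00041 to 0.15). Its interaction was -0.78 ± 0.24 (adjusted p = 0.192, and 0.0228 with the replicate block, over a range of 0.0228 to 0.83). The myeloid factor gene cebpa fell with leflunomide in control embryos by 0.46 ± 0.06 (63.7 to 46.3 CPM, adjusted p = 8.05e-05). In tif1g embryos its change was -0.18 ± 0.06 (adjusted p = 0.206, and 0.0455 with the replicate block, over a range of 0.0455 to 0.541), and its interaction was 0.28 ± 0.09 (adjusted p = 0.204, and 0.032 with the replicate block, over a range of 0.032 to 0.785).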
